A study of Mus musculus with 6 samples.

How the data were processed

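Inguinal fat of 3 group-housed and 3 single-housed male mice was profiled by RNA-seq. Per the labels' protocols, total RNA was extracted from frozen tissue with TRIzol, treated with DNase I and purified on RNeasy columns, RNA integrity numbers were above 8, and libraries followed the protocol of the provider Genewiz. The submitters' processing notes name the genome build mm39. The aligner, the counting program, the annotation release, and whether counting used the strand are not given in the sources used here. The labels say that the samples are 6 mice. They do not say whether mice of a group shared a cage or litter, and mice from a shared cage would not be independent.

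The deposited table holds raw counts and FPKM for 56691 genes in each of the 6 libraries, with gene identifiers, symbols, mm39 coordinates and GO and KEGG terms. The count columns hold whole-number counts of reads per gene that the authors did not normalize, per the file headers and the values, and a second deposited sheet holds the same counts. The FPKM columns hold the authors' counts divided by the summed exon length of the gene and by the library's total count, as a check of the values showed: 100% of them equalled that quotient within 0.0051. The deposited FPKM thus carry no correction for composition between libraries. A further 24 columns of per-sample values, whose names give other tissues, match no sample of this series and were not used here. A total of 2639 rows had no symbol. They carry gene identifiers and stayed in the gene test, and they took between 0.118% and 0.171% of the counts of a library. Coordinates are those of the deposited table. The reference annotation at hand is of build GRCm38, where only 2.83% of 52073 shared identifiers had the same start and end, so its coordinates were not used here.

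Counts were tested with edgeR 4.0.16 (R 4.3.3), with filterByExpr, TMM normalization and the quasi-likelihood F test, two-sided, and Benjamini-Hochberg adjustment over 18085 genes. A gene passed at an adjusted p below 0.05. The design written before the data were examined foresaw limma on log2(FPKM + 1) if the tables held only FPKM and edgeR if they held counts. Since they held counts, edgeR was used, and limma on log2(FPKM + 1) became an alternative. Log2 fold changes are single minus group housing from edgeR, with a standard error computed as the absolute log2 fold change divided by the square root of the F statistic. FPKM levels are given as mean ± SD of 3 libraries, group housing first. Fold differences are the edgeR estimates, not ratios of the FPKM means.

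A total of 38 gene lists (844 distinct genes, of which 9 are not in the table under that symbol) were fixed before the data were examined. They cover sympathetic signalling, thermogenesis, lipid and glucose metabolism, stress, clock, inflammation, matrix, and markers of each cell type that the fat pad or a neighbouring tissue could hold. Lists were tested with camera in limma 3.58.1 on log2(FPKM + 1) of the 14184 genes with a mean FPKM of at least 1, with a preset correlation of 0.01 and adjustment over the 35 lists that had at least 5 such members. The lists of epididymal fat and mesothelial markers (2 members above the minimum), keratinocyte and skin markers (4) and mammary and luminal epithelial markers (3) were not tested. Camera was repeated with the correlation estimated per list, and fry was run on the same lists. Camera asks whether a list's genes differ from other genes, and fry whether they move at all. Annotation terms of the deposited table with 15 to 300 tested genes went through camera in the same way. Medians of lists are of edgeR log2 fold changes unless the log2(FPKM + 1) scale is named. On that scale the median over all genes was -0.09, and with TMM factors on FPKM it was 0.03. Many lists share genes, so their results are not independent.

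The genes named in the text follow a rule fixed before the data were examined. It takes up to 12 genes per direction past the threshold with non-overlapping groups or, where fewer pass, up to 8 per direction of smallest p, leaving out predicted genes. It adds the 4 members of smallest p of each list that passed, and 12 genes chosen for adipocyte function whatever their values. No gene passed, so the genes of smallest p stand as not past the threshold.

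The tests were tried on simulated counts for the comparison of single with group housing, drawn for 18085 genes with 200 of them changed. The edgeR test recovered 28.6% of genes changed 2-fold and 91.7% of those changed 4-fold, and called 10 unchanged genes. DESeq2 1.42.0 recovered 58.9% and 97.9%, and called 48 unchanged genes. In the real counts edgeR estimated a biological coefficient of variation of 0.265. Of 34 simulated lists, 3 were shifted by 0.6 on the log2 scale and all 3 passed camera, and of 26 unshifted lists 1 passed. The remaining lists shared genes with a shifted list and were counted as neither. Genes were drawn independently of each other there. In the real data the estimated correlation was 0.25 for the thermogenic list and 0.96 for ribosomal proteins. The simulation therefore does not give camera's rate of false calls in these data. Pairs of libraries were compared by a chi-square test of their counts, and none differed by as little as sampling noise.

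Alternatives were DESeq2, other size factors, no filter on low counts, limma on log2 FPKM with other pseudocounts, filters and scalings, library weights, a replicate block, and leaving out each library. Covariates for the mean level of skeletal muscle or B cell markers, leaving out the 2 libraries with most muscle transcripts, and camera on TMM-normalized log2 CPM were added after seeing the data. Library depth was 21410779 to 35318376 counts. Counts are reads without molecular identifiers, so a limit of detection of 3 counts covers counting error only. Figures were drawn with matplotlib 3.10.9.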

Results

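Transcript levels were measured by bulk RNA-seq in inguinal white adipose tissue (iWAT), the subcutaneous fat pad of the groin, of 6 male mice of the inbred strain C57BL/6J. The mice were 8 weeks old at the start and were then kept for 8 weeks either with 4 to 6 mice per cage (group housing, 3 mice) or with 1 mouse per cage (single housing, 3 mice). Each mouse gave 1 library. Counts assigned to genes came to 22041314, 22002000 and 33982084 in group-housed libraries 1, 2 and 3, and to 35318376, 21410779 and 24781206 in single-housed libraries 1, 2 and 3. Genes of the mitochondrial chromosome took 6.58% ± 0.83 of the counts under group housing and 10.4% ± 1.5 under single housing (SD, n = 3 each). The 3 single-housed values all lay above the 3 group-housed values, which gave a two-sided exact permutation p = 0.1, the smallest that 3 against 3 allows.

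The first principal component held 61.0% of the variance between libraries and did not follow housing. It set single-housed library 3 (82.8) and group-housed library 2 (30.0) apart from group-housed library 3 (-50.4). The second component, with 17.7%, was below 0 in the 3 group-housed libraries and above 0 in the 3 single-housed ones. Skeletal muscle markers had a mean of 7.63 log2 CPM in single-housed library 3, 5.67 in group-housed library 2 and 4.12 in group-housed library 1, against 1.36 in group-housed library 3 and 1.85 and 1.66 in single-housed libraries 1 and 2. The inguinal pad holds a lymph node, and the B and plasma cell markers had their lowest mean in single-housed library 3 (6.14 log2 CPM), against 6.77 to 7.39 in the other 5 libraries. T and NK cell markers were also lowest there, at 3.70 log2 CPM against 4.41 to 5.29.

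**Figure D1:**
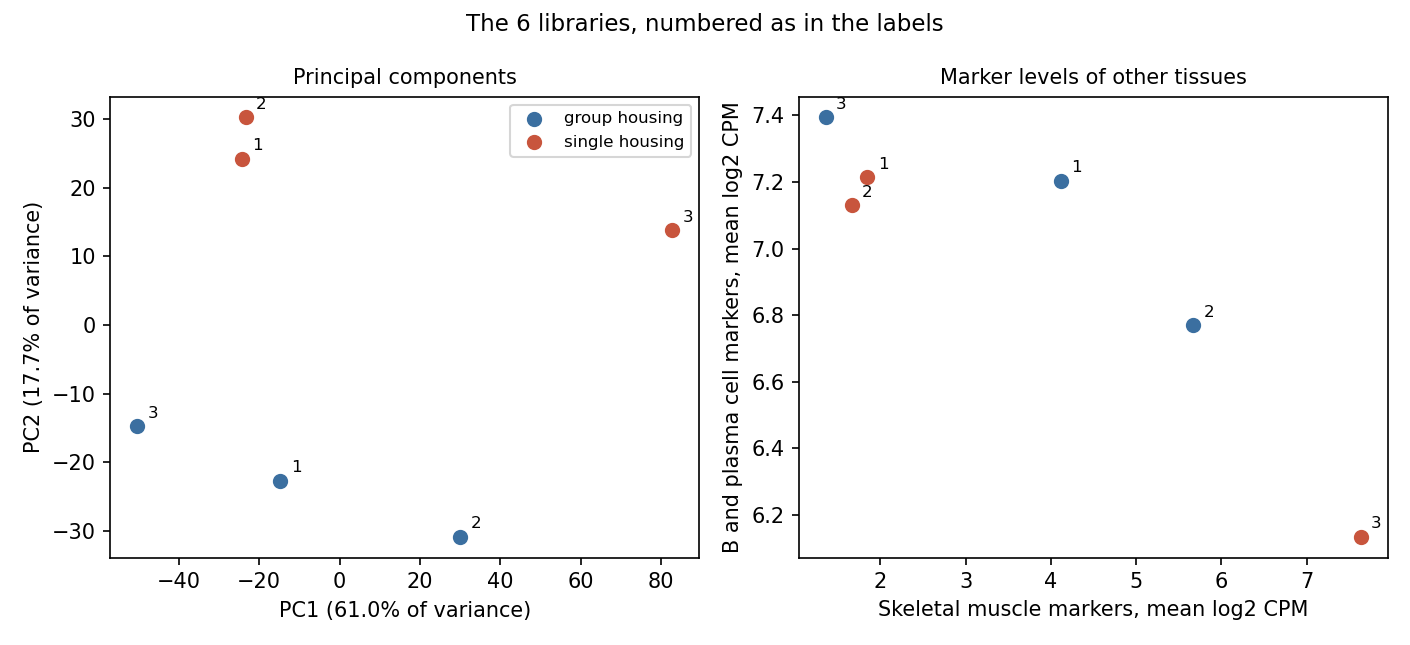
Left: the 6 libraries on the first and second principal components of log2 CPM (61.0% and 17.7% of the variance). Right: the mean log2 CPM of skeletal muscle markers (horizontal) and of B and plasma cell markers (vertical) in each library, numbered as in the labels and coloured by housing. The second component separates the groups, and single-housed library 3 has the most muscle transcripts (7.63) and the fewest B cell transcripts (6.14).

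The series compares single with group housing and, by its title, is about social isolation, blood glucose and sympathetic activation of this fat depot. In iWAT of single-housed mice, genes of heat-producing (brown and beige) adipocytes and of mitochondrial fatty acid oxidation rose as groups, and genes induced by interferon and genes of inflammatory cytokines and chemokines fell as groups. These calls took a preset correlation between genes, and none held with the correlation estimated from the data (adjusted p = 0.256 for the thermogenic, oxidation and interferon lists and 0.320 for the inflammatory list). Ucp1, the uncoupling protein through which thermogenic adipocytes release heat, stood at 54.1 ± 4.65 FPKM under group housing and 219 ± 50.6 FPKM under single housing (SD, n = 3 each), a 4.3-fold difference. The chemokine gene Ccl2 stood at 23.0 ± 14.2 and 2.23 ± 0.69 FPKM, a 9.62-fold difference in the opposite direction. Groups of genes passed the list test with a preset correlation, while no single gene passed the test over all genes.

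Among 18085 genes tested with edgeR's quasi-likelihood test, 0 had a Benjamini-Hochberg adjusted p below 0.05, and the smallest adjusted p was 0.120. At an unadjusted p below 0.05 there were 1259 genes (631 higher and 628 lower in single housing), where 904 would come by chance. Of the 10 splits of the libraries into 3 and 3, 4 gave as many, with up to 2546. The count therefore does not show an excess over chance. DESeq2 called 207 genes (78 higher, 129 lower) on the same counts, and in data simulated with unchanged genes it also called more of those (48) than edgeR did (10). The 3 values of one group lay wholly above those of the other for 2422 genes (13.4%), where chance gives 10%. How widely this share varies by chance was not tested. With the mean level of skeletal muscle markers as a covariate, chosen after seeing the data, edgeR called 1028 genes (457 higher, 571 lower), and without group-housed library 2 and single-housed library 3 it called 22 (8 higher, 14 lower).

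The genes of smallest p with higher levels in all 3 single-housed libraries were Ucp1, Acot11, Gnao1, Lgr6, S100b, Cxadr, Pank1 and Cish, none of them past the threshold in edgeR. Ucp1 (ENSMUSG00000031710; mm39 chromosome 8, 84016981 to 84025081) had a log2 fold change of 2.10 ± 0.21 (SE; edgeR adjusted p = 0.120, DESeq2 adjusted p = 3.05e-17). Acot11, an acyl-CoA thioesterase first described in brown fat (ENSMUSG00000034853; chromosome 4, 106601752 to 106662195), stood at 4.59 ± 1.32 and 13.5 ± 2.94 FPKM, with a log2 fold change of 1.65 ± 0.21. Pank1, a pantothenate kinase of coenzyme A synthesis (chromosome 19, 34784340 to 34856855), stood at 2.64 ± 0.31 and 5.79 ± 0.95 FPKM. Cish, an inhibitor of cytokine signalling that is induced through STAT5 (chromosome 9, 107173225 to 107179983), stood at 1.76 ± 0.25 and 9.81 ± 4.66 FPKM. Gnao1, a G protein alpha subunit, stood at 0.79 ± 0.01 and 1.89 ± 0.25 FPKM. Lgr6 was near the limit of detection, with 2, 2 and 8 counts in the group-housed and 58, 30 and 61 counts in the single-housed libraries. S100b (2.0 ± 0.11 and 6.42 ± 1.12 FPKM) and Cxadr (2.45 ± 0.43 and 5.07 ± 1.05 FPKM) overlap Dip2a and Btg3 on the opposite strand, and whether counting used the strand is not given in the sources used here. The values of Cish, and of Acadvl, Etfdh, Zfp36, Junb, Manf, Gpd2, Gpd1, Cidea, Adcy3, Pde4d, Erg, Lipe and Adrb3 below, are also uncertain, since each overlaps another gene with counts.

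The corresponding genes with lower levels in all 3 single-housed libraries were Serpinb9b, Ms4a6d, Ccl12, Slfn4, Oas1a, Chil3, Lgals3 and Timp1, again none past the threshold in edgeR. Serpinb9b, a serine protease inhibitor gene (ENSMUSG00000021403; chromosome 13, 33211399 to 33225867), had the smallest p of all genes, with 2.45 ± 0.67 and 0.13 ± 0.06 FPKM and a log2 fold change of -4.20 ± 0.37 (edgeR adjusted p = 0.120). Slfn4, a myeloid schlafen gene (chromosome 11, 83066012 to 83081042), stood at 17.3 ± 10.9 and 0.60 ± 0.10 FPKM, a 26.6-fold difference. Ccl12, a monocyte chemoattractant (chromosome 11, 81992671 to 81994226), stood at 54.1 ± 24.6 and 5.65 ± 1.63 FPKM. Chil3, a chitinase-like protein of activated macrophages (chromosome 3, 106054870 to 106074880), stood at 12.1 ± 6.62 and 1.32 ± 0.21 FPKM. Lgals3, the macrophage lectin galectin-3 (chromosome 14, 47605208 to 47623617), stood at 42.1 ± 9.03 and 17.4 ± 1.02 FPKM, and Ms4a6d (chromosome 19, 11563968 to 11582213) at 15.2 ± 4.53 and 3.56 ± 0.03 FPKM. Timp1, an inhibitor of metalloproteinases (chromosome X, 20736405 to 20740974), stood at 8.30 ± 4.04 and 0.75 ± 0.10 FPKM and overlaps Syn1 on the opposite strand. Serpinb9b, Ms4a6d, Slfn4, Oas1a and the chemokine genes belong to families of close copies, between which reads can be split, so their values are uncertain to that extent.

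**Figure D2:**
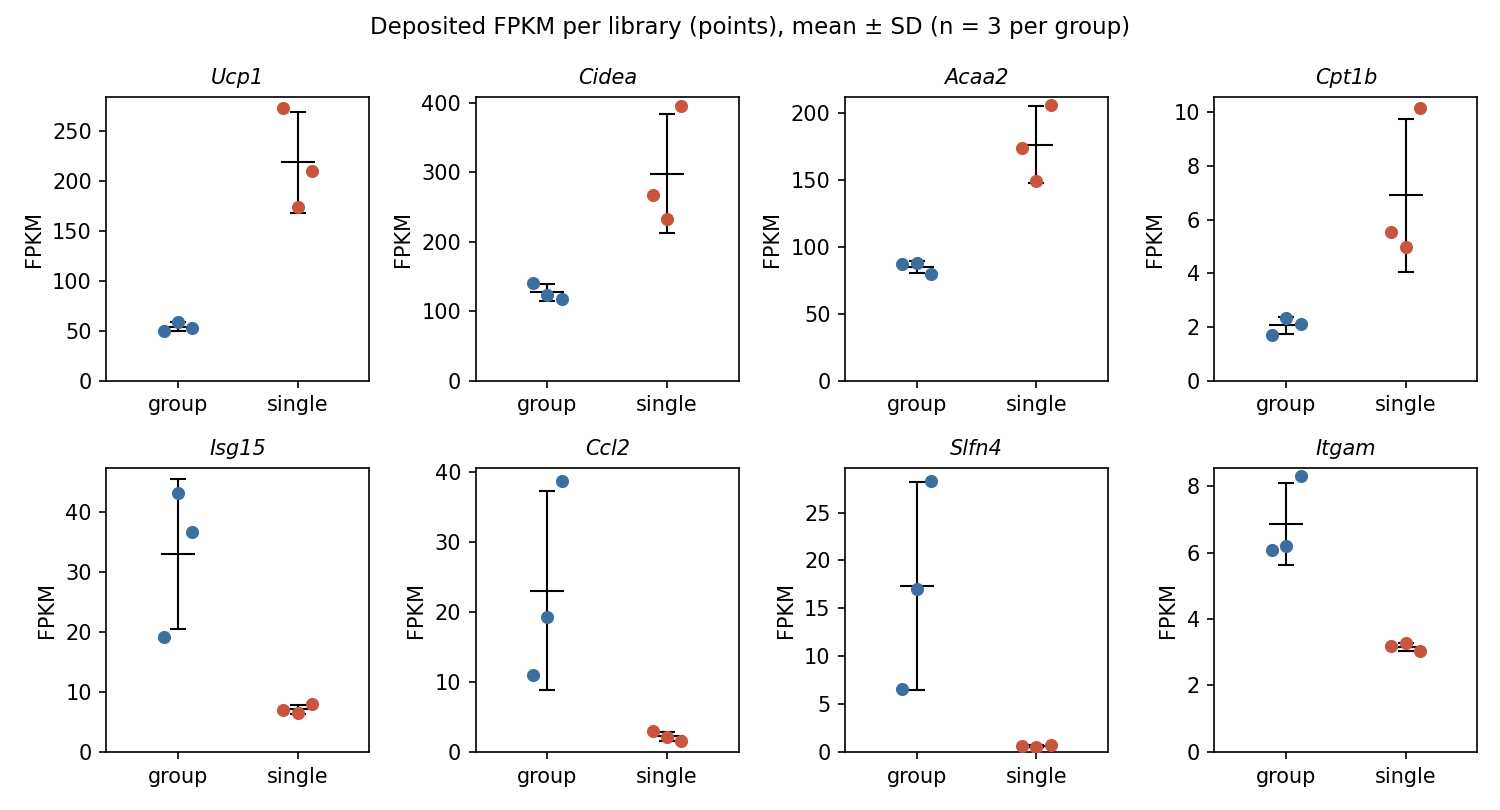
Deposited FPKM of 8 genes in each library (points; blue, group housing; red, single housing), with the mean and SD of 3 libraries per group as a horizontal mark and error bars; each vertical axis starts at 0. Ucp1, Cidea, Acaa2 and Cpt1b lie higher in all 3 single-housed libraries, and Isg15, Ccl2, Slfn4 and Itgam lie lower; no gene passed edgeR's adjusted threshold (smallest adjusted p = 0.120).

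Of 38 gene lists fixed before the data were examined, 35 had enough expressed members, and 25 passed limma's camera test with a preset correlation (16 up, 9 down in single housing). With TMM scaling of the FPKM 25 lists also passed (13 up, 12 down), 22 of them the same. The adrenergic, circadian clock and Schwann cell lists no longer passed there, and the B cell, T cell and glucocorticoid lists passed downward. With the correlation estimated from the data, 0 lists passed (smallest adjusted p = 0.256, with 6 lists at an unadjusted p below 0.05), and limma's fry test, which asks whether a list moves on balance, also called 0 (smallest adjusted p = 0.0672, with 10 lists at an unadjusted p below 0.05). Fry's test for change in either direction called 7. The medians given for each list are of edgeR log2 fold changes on counts, while camera ran on log2(FPKM + 1), where the medians of rising lists were smaller and the median of all genes was -0.09.

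Thermogenic and beige adipocyte genes rose in single-housed mice (30 tested, median log2 fold change 0.82 on counts and 0.43 on log2(FPKM + 1), 28 of 30 above 0; camera adjusted p = 3.57e-21). The adjusted p was 0.256 with an estimated correlation. The 2 members below 0 were Tmem26 (log2 fold change -0.56 ± 0.30) and Tnfrsf9 (-0.44 ± 0.40). Tbx1 (0.13 ± 0.27), Gatm (0.14 ± 0.29) and Ckb (0.08 ± 0.24) differed little. The test is of the whole list and does not tell beige-specific genes from other thermogenic genes. There were 14 higher and 0 lower members adjusted over the list alone, against 0 over all genes in edgeR and 11 higher in DESeq2. Beside Ucp1 and Acot11 they included Otop1, a proton channel gene (9.20 ± 1.33 and 19.7 ± 4.10 FPKM), and Cpt1b, which carries fatty acids into mitochondria (2.06 ± 0.32 and 6.90 ± 2.84 FPKM). Cpt1b is also expressed in muscle. Single-housed library 3, with the most muscle transcripts, had the highest Cpt1b level, at 10.2 FPKM against 5.54 and 5.0 in single-housed libraries 1 and 2. Brown adipose tissue markers, of which 7 of 18 are also in the thermogenic list, rose too (15 tested, median log2 fold change 0.87; adjusted p = 5.93e-14, and adjusted p = 0.256 with an estimated correlation). Of these, 7 were higher adjusted over the list alone (7 in DESeq2, 0 over all genes in edgeR), Ucp1, S100b, Pank1 and Otop1 having the smallest p. Among those 7, Ucp1, Otop1, Elovl3, Cidea and Cox7a1 are also in the thermogenic list. Apart from S100b and Pank1, members not shared with it ran from -0.74 (Epsti1) to 0.41 (Ebf3). The rise of this list thus largely repeats that of the thermogenic list.

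Mitochondrial fatty acid oxidation rose (23 tested, median log2 fold change 0.59, 21 of 23 above 0; adjusted p = 7.58e-21, and adjusted p = 0.256 with an estimated correlation). The list held 10 higher members adjusted over the list alone, against 0 over all genes in edgeR and 8 in DESeq2. Acaa2, the thiolase of the last step of beta-oxidation, stood at 84.7 ± 4.39 and 176 ± 28.6 FPKM. Acadvl, the very-long-chain acyl-CoA dehydrogenase, stood at 89.4 ± 8.21 and 157 ± 26.6 FPKM, and Etfdh, which passes electrons on to ubiquinone, at 17.2 ± 1.68 and 31.7 ± 6.83 FPKM. The 15 mitochondrially encoded transcripts rose as a group and were all above 0, with a median log2 fold change of 0.72 (adjusted p = 1.25e-14, and adjusted p = 0.256 with an estimated correlation). Of these, 0 passed adjusted over the list alone or over all genes in edgeR, with 11 at an unadjusted p below 0.05 and 3 higher in DESeq2. Among them mt-Rnr2, a ribosomal RNA, stood at 730 ± 178 and 1575 ± 408 FPKM, and mt-Nd5, a subunit of complex I that overlaps mt-Nd6, at 2004 ± 475 and 3609 ± 565 FPKM. Nuclear-encoded oxidative phosphorylation genes also rose (43 tested, median log2 fold change 0.20, 39 above 0; adjusted p = 5e-10, and adjusted p = 0.415 with an estimated correlation). Uqcrc1, of complex III, stood at 50.2 ± 3.18 and 74.8 ± 10.6 FPKM. Adjusted over the list alone 0 oxidative phosphorylation genes passed in edgeR (6 at an unadjusted p below 0.05, all higher; 0 in DESeq2). The list's adjusted p was 0.0765 without group-housed library 3 and 0.409 with library weights. The genes named in this paragraph all had their highest level in single-housed library 3, which had the most muscle transcripts. There Acaa2 stood at 206 FPKM, against 173 and 149 FPKM in single-housed libraries 1 and 2. The calls of these lists held without that library and group-housed library 2. How far muscle added to the size of the rises was not tested.

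Interferon-stimulated genes fell in single-housed mice, 29 of 30 having a log2 fold change below 0 (median -0.74; camera adjusted p = 1.41e-19, and adjusted p = 0.256 with an estimated correlation). Of the 30, 20 were lower and 0 higher adjusted over the list alone, against 0 over all genes in edgeR and 16 lower in DESeq2. Isg15, a ubiquitin-like protein induced by interferon, stood at 33.0 ± 12.5 and 7.12 ± 0.75 FPKM. Oas1a and Oas2, which sense viral double-stranded RNA, stood at 12.5 ± 2.17 and 3.98 ± 0.53 FPKM and at 11.5 ± 2.40 and 4.67 ± 0.34 FPKM. Irf7, a transcription factor of the interferon response that overlaps Phrf1 on the opposite strand, stood at 18.7 ± 3.25 and 7.08 ± 1.61 FPKM.

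Inflammatory cytokines and chemokines fell (22 tested, median log2 fold change -0.71, 19 below 0; adjusted p = 8.20e-06, and adjusted p = 0.320 with an estimated correlation). When adjusted over the list alone, 8 were lower and 1 higher, against 0 over all genes in edgeR and 7 lower and 1 higher in DESeq2. The monocyte-attracting chemokines Ccl2, Ccl7 and Ccl8 had log2 fold changes of -3.27 ± 0.46, -3.84 ± 0.54 and -1.59 ± 0.28. Saa3, an acute-phase protein, had 146, 357 and 455 counts in the group-housed and 4, 1 and 13 counts in the single-housed libraries. Macrophage and monocyte markers fell (24 tested, median log2 fold change -0.40, 19 below 0; adjusted p = 8.59e-07, and adjusted p = 0.256 with an estimated correlation). Of the 24, 7 were lower adjusted over the list alone, against 0 over all genes in edgeR and 4 in DESeq2. Itgam, the integrin CD11b, stood at 6.86 ± 1.24 and 3.16 ± 0.12 FPKM. Fcgr1, an Fc receptor, stood at 6.24 ± 1.69 and 1.62 ± 0.34 FPKM, and Ccr2, the receptor of Ccl2 on monocytes, at 12.6 ± 2.44 and 7.37 ± 1.21 FPKM.

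Dendritic cell, neutrophil and mast cell markers fell (17 tested, median log2 fold change -0.44; adjusted p = 0.00625, and adjusted p = 0.407 with an estimated correlation). There were 3 lower adjusted over the list alone, 3 in DESeq2 and 0 over all genes in edgeR. The neutrophil gene S100a9 stood at 30.2 ± 14.5 and 6.27 ± 3.79 FPKM. This call ended without group-housed library 2 and single-housed library 3 (adjusted p = 0.132), with library weights (0.216) and with the B cell level as a covariate (0.0535).

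Cytosolic ribosomal proteins fell, all 40 lying below 0 (median log2 fold change -0.29; adjusted p = 4.43e-07, and adjusted p = 0.457 with an estimated correlation). Of the 40, 0 passed adjusted over the list alone or over all genes in edgeR (2 at an unadjusted p below 0.05, 0 in DESeq2). Rplp1 stood at 859, 535 and 650 FPKM in group-housed libraries 1, 2 and 3 and at 531, 516 and 336 FPKM in the single-housed ones. Its lowest level was in single-housed library 3, where B and T cell markers were also lowest. The list's call held without that library and with the B cell level as a covariate. A part of lymph node content in the fall was not tested. Heat shock and unfolded protein response genes fell (25 tested, median log2 fold change -0.19; adjusted p = 1.47e-05, and adjusted p = 0.256 with an estimated correlation). There were 4 lower adjusted over the list alone, 5 in DESeq2 and 0 over all genes in edgeR. Those 4, Manf, Creld2, Sdf2l1 and Pdia4, encode proteins of the endoplasmic reticulum, and Creld2 stood at 27.5 ± 0.86 and 18.2 ± 0.22 FPKM. Genes of the cAMP and immediate-early response fell (28 tested, median log2 fold change -0.30, 25 below 0; adjusted p = 8.95e-06, and adjusted p = 0.256 with an estimated correlation). In that list 0 passed adjusted over the list alone or over all genes in edgeR (5 lower and 1 higher at an unadjusted p below 0.05, 1 lower in DESeq2). Among them Zfp36, which destabilises cytokine mRNAs, stood at 27.5 ± 0.76 and 17.9 ± 2.99 FPKM, Junb at 11.3 ± 2.55 and 6.26 ± 2.23 FPKM, and Nr4a2, with the opposite sign, at 1.31 ± 0.06 and 1.73 ± 0.22 FPKM.

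Lists of adipocyte metabolism rose too, with smaller medians. Glyceroneogenesis and gluconeogenic precursor genes had a median log2 fold change of 0.24 (19 tested; adjusted p = 1.80e-05, and adjusted p = 0.337 with an estimated correlation). Ldhb (37.1 ± 5.16 and 62.5 ± 6.37 FPKM) and Gpd2 (33.6 ± 1.65 and 51.8 ± 6.16 FPKM) were higher adjusted over the list alone, with 3 higher in DESeq2 and 0 over all genes in edgeR. Glycolysis and glucose uptake genes had a median of 0.28 (20 tested; adjusted p = 1.49e-05, and adjusted p = 0.380 with an estimated correlation). Cholesterol synthesis genes had 0.28 (21 tested; adjusted p = 0.000161, and adjusted p = 0.407 with an estimated correlation), and triglyceride synthesis and uptake genes 0.28 (20 tested; adjusted p = 2.81e-05, and adjusted p = 0.407 with an estimated correlation). De novo fatty acid synthesis genes had a median of 0.22 (21 tested; adjusted p = 0.000946, and adjusted p = 0.415 with an estimated correlation). Lipolysis genes had a median of 0.32 (16 tested, 14 above 0; adjusted p = 0.000503, and adjusted p = 0.415 with an estimated correlation). In these 5 lists 0 members passed adjusted over the list alone or over all genes in edgeR, and 0 in DESeq2. At an unadjusted p below 0.05 they held 3, 2, 5, 0 and 0 members in that order, all higher except Fabp5 of the triglyceride list (92.5 ± 21.5 and 60.4 ± 8.15 FPKM). Hk2, a hexokinase, stood at 30.7 ± 1.20 and 39.9 ± 4.76 FPKM, and Gpd1, which makes glycerol 3-phosphate, at 524 ± 70.9 and 721 ± 88.0 FPKM. Mature adipocyte markers, 17 of 20 shared with other lists, had a median of 0.30 (20 tested; adjusted p = 4.66e-05, and adjusted p = 0.415 with an estimated correlation). Cidea, a lipid droplet protein (127 ± 12.1 and 298 ± 85.6 FPKM), was the 1 member higher when adjusted over the list alone, 1 in DESeq2 and 0 over all genes in edgeR.

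On log2(FPKM + 1) the medians were 0.16 for glyceroneogenesis, 0.16 for glycolysis, 0.16 for cholesterol synthesis, 0.20 for triglyceride synthesis, 0.14 for de novo synthesis, 0.23 for lipolysis and 0.22 for mature adipocyte markers. The calls of 6 of these lists ended when a single library was left out. That of glyceroneogenesis held in all 17 alternatives, with medians from 0.0090 to 0.33 and adjusted p up to 0.0341. Without group-housed library 3 the adjusted p was 0.265 for lipolysis, 0.113 for de novo synthesis, 0.0678 for triglyceride synthesis and 0.345 for mature adipocyte markers, and without single-housed library 3 it was 0.184, 0.184, 0.0720 and 0.0553 for the same lists, 0.159 for glycolysis and 0.123 for cholesterol synthesis.

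None of the genes named in advance for adipocyte function passed edgeR's adjusted threshold. The lipases Pnpla2 (286 ± 88.2 and 383 ± 93.7 FPKM, adjusted p = 0.825) and Lipe (139 ± 27.6 and 145 ± 13.9 FPKM, adjusted p = 0.920) did not pass, nor did the beta-3 adrenergic receptor gene Adrb3 (97.0 ± 43.6 and 90.7 ± 20.5 FPKM, adjusted p = 0.990). Leptin (Lep) stood at 63.4 ± 15.6 and 93.6 ± 31.2 FPKM (log2 fold change 0.67 ± 0.33) and adiponectin (Adipoq) at 1031 ± 304 and 1000 ± 188 FPKM (0.04 ± 0.31). The insulin-responsive glucose transporter Slc2a4 stood at 57.9 ± 10.7 and 71.6 ± 10.6 FPKM, fatty acid synthase (Fasn) at 637 ± 50.5 and 748 ± 110 FPKM, and Acly, which supplies cytosolic acetyl-CoA, at 542 ± 84.7 and 521 ± 89.3 FPKM. Pck1 stood at 493 ± 196 and 493 ± 36.4 FPKM and the coactivator Ppargc1a at 2.63 ± 0.42 and 3.40 ± 0.30 FPKM (log2 fold change 0.46 ± 0.18, adjusted p = 0.689). The signs of Adipoq, Lipe, Adrb3, Acly and Pck1 turned under some other processing. Th, the rate-limiting enzyme of noradrenaline synthesis, had 2 counts in group-housed library 1 and 0 in the other 5 libraries. It was not detectable, so it gives no measure of sympathetic input to the fat.

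Adrenergic receptor and cAMP signalling genes passed the test upward (25 tested; adjusted p = 0.00822, and adjusted p = 0.317 with an estimated correlation), with 13 members above 0 and 12 below. Their median log2 fold change was 0.10 on counts and -0.003 on log2(FPKM + 1), so the median and the test differed in sign on the latter scale. Adjusted over the list alone 0 passed, as over all genes in edgeR and in DESeq2, and 4 were at an unadjusted p below 0.05, all higher. These were Adra1a (1.72 ± 0.32 and 2.87 ± 0.46 FPKM) and Adrb1 (1.11 ± 0.18 and 1.67 ± 0.39 FPKM), which encode receptors, Adcy3 (3.90 ± 0.62 and 6.46 ± 1.38 FPKM), which makes cAMP, and Pde4d (1.83 ± 0.32 and 2.44 ± 0.29 FPKM), which breaks it down. The call ended in 7 of 17 alternatives, among them without group-housed library 1 (adjusted p = 0.0622) and without single-housed library 3 (0.103). Sympathetic neuron and axon markers did not pass, and only 6 of the 23 were expressed enough to be tested (median log2 fold change 0.15, adjusted p = 0.228). With so few members the test says little about sympathetic nerves in the fat.

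Endothelial and lymphatic markers rose (18 tested, median log2 fold change 0.43, 15 above 0; adjusted p = 8.56e-07, and adjusted p = 0.256 with an estimated correlation). Adjusted over the list alone 0 passed, as over all genes in edgeR and in DESeq2, with 4 higher at an unadjusted p below 0.05. Kdr, the receptor of vascular endothelial growth factor, stood at 16.4 ± 2.04 and 24.7 ± 3.37 FPKM and Erg, an endothelial transcription factor, at 7.33 ± 0.22 and 10.01 ± 0.80 FPKM. Extracellular matrix genes fell (34 tested, median log2 fold change -0.22; adjusted p = 0.000220, and adjusted p = 0.415 with an estimated correlation). Timp1 and Thbs1 (5.89 ± 2.16 and 2.46 ± 0.25 FPKM) were the 2 members lower when adjusted over the list alone, 2 in DESeq2 and 0 over all genes in edgeR. Without group-housed library 2 the adjusted p of the matrix list was 0.218, and without single-housed library 1 it was 0.114.

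The adipose progenitor and fibroblast, circadian clock and Schwann cell lists passed narrowly, each at an adjusted p of 0.0459. Progenitor and fibroblast markers fell (19 tested, median log2 fold change -0.14; adjusted p = 0.415 with an estimated correlation). They had 0 lower when adjusted over the list alone or over all genes in edgeR, 2 at an unadjusted p below 0.05 and 0 in DESeq2. Circadian clock genes passed upward (18 tested, median 0.16 on counts and 0.035 on log2(FPKM + 1); adjusted p = 0.285 with an estimated correlation), with the clock output factor Hlf (1.06 ± 0.11 and 2.04 ± 0.27 FPKM) as the 1 member higher when adjusted over the list alone and 1 in DESeq2. At an unadjusted p below 0.05 the clock list held 2 higher members and 1 lower, Per1 (6.68 ± 0.17 and 4.75 ± 0.89 FPKM, log2 fold change -0.41 ± 0.14), and Nr1d1, which overlaps Thra on the opposite strand, also had a negative log2 fold change (-0.54 ± 0.25). Schwann cell markers passed upward (13 tested, median 0.16 on counts and 0.011 on log2(FPKM + 1); adjusted p = 0.317 with an estimated correlation), with S100b, also a brown fat marker, as the 1 member higher when adjusted over the list alone and 1 in DESeq2. The 3 calls ended in 6, 11 and 11 of 17 alternatives, and with library weights the test of the Schwann list pointed down (median -0.10, adjusted p = 0.825).

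**Figure D3:**
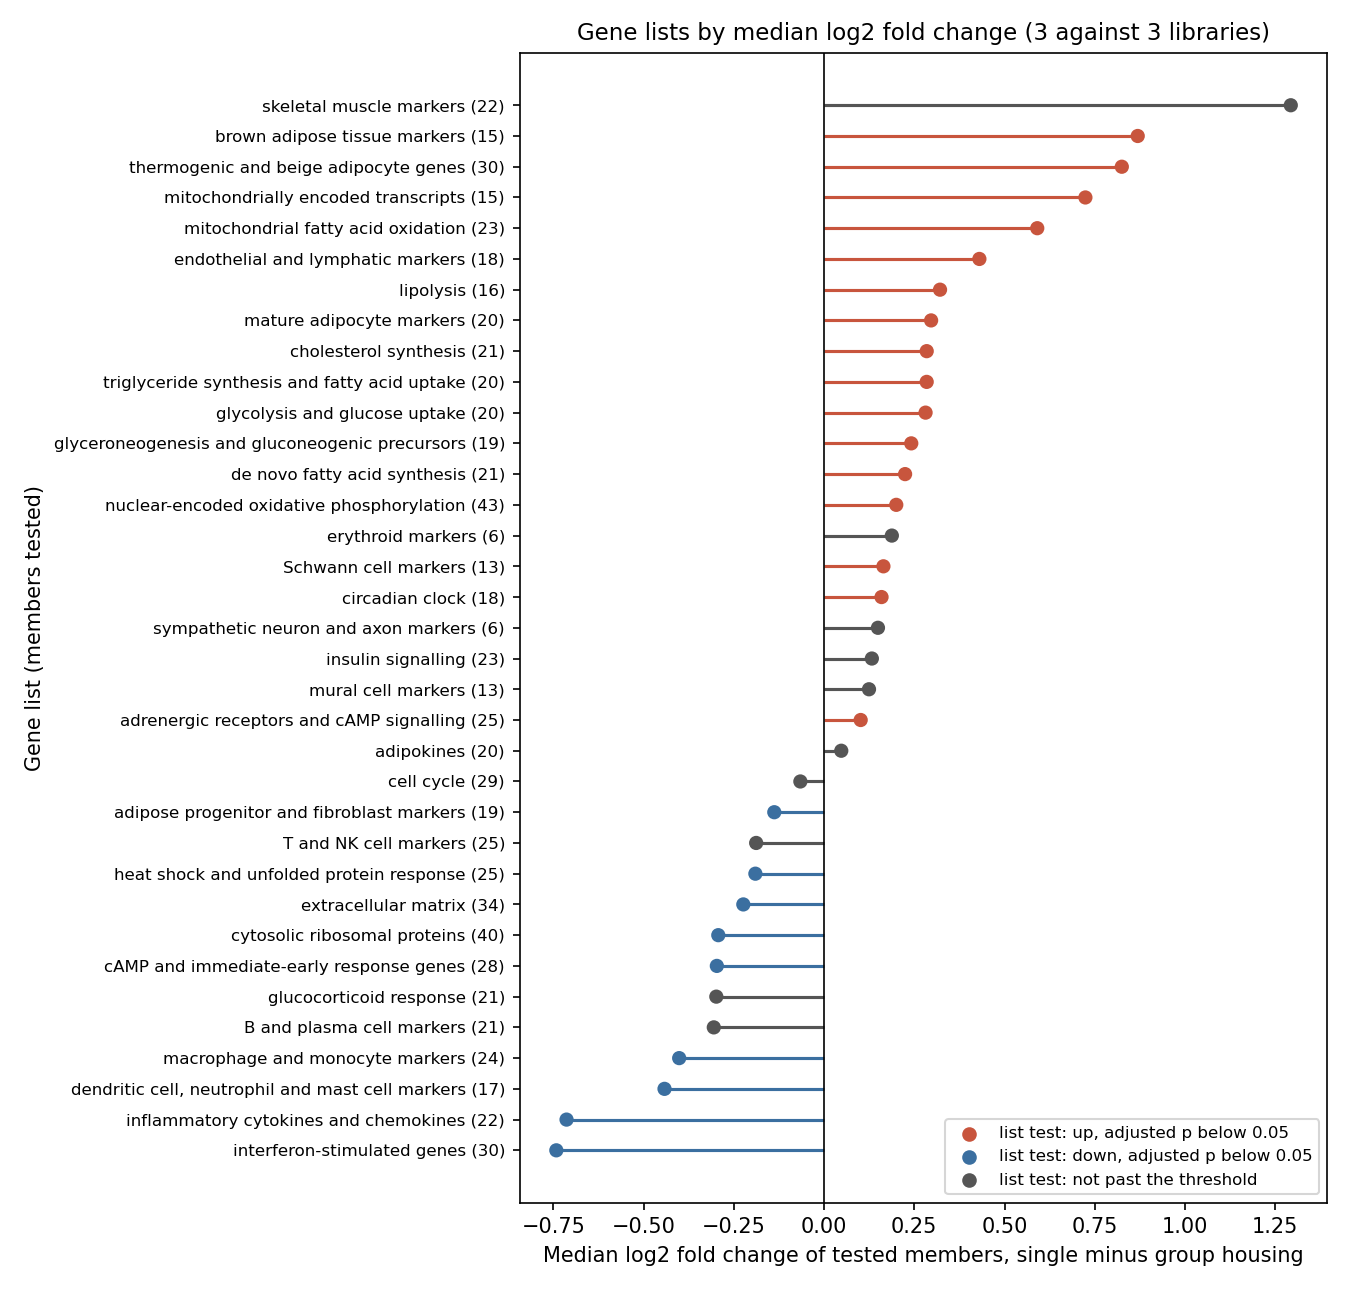
Median log2 fold change (single minus group housing, edgeR) of the tested members of each of 35 gene lists; the number of members tested stands in parentheses. Red and blue points mark lists that passed limma's camera test upward and downward with a preset correlation, and grey points those that did not. Interferon-stimulated genes (-0.74) lie lowest, brown adipose markers (0.87) lie highest among the lists that passed, and the grey skeletal muscle list (1.29) had a median of -0.05 on log2(FPKM + 1).

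The other 10 lists did not pass. Skeletal muscle markers had a median log2 fold change of 1.29 on counts and -0.05 on log2(FPKM + 1) (adjusted p = 0.0593), and without single-housed library 3 the median on the latter scale was -2.53. B and plasma cell markers had a median of -0.31 (adjusted p = 0.136) and passed downward in 8 of 17 alternatives, among them with TMM scaling of the FPKM (adjusted p = 0.00591) and with the muscle level as a covariate (0.000203). T and NK cell markers had a median of -0.19 (adjusted p = 0.288) and passed downward in 6 alternatives and upward in 2. The muscle list passed upward in 4 and downward in 4. Glucocorticoid response genes had a median of -0.30 (21 tested; adjusted p = 0.0872), and the list passed in 10 alternatives. Insulin signalling genes had a median of 0.13 (adjusted p = 0.0574), erythroid markers 0.19 (adjusted p = 0.0502) and mural cell markers 0.12 (adjusted p = 0.149), and they passed upward in 6, 7 and 2 alternatives. Adipokines had a median of 0.05 while the test pointed down (adjusted p = 0.851), and 3 of them were lower when adjusted over the list alone, 3 in DESeq2 and 0 over all genes in edgeR. The adipokine list passed downward in 3 alternatives. Cell cycle genes had a median of -0.07 while the test pointed up (adjusted p = 0.851), and they passed downward in 2 alternatives.

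Annotation terms extended the comparison beyond the fixed lists. Of 1716 GO and KEGG terms with 15 to 300 tested genes, 245 passed camera with a preset correlation (142 up, 103 down) and 0 passed with an estimated correlation (smallest adjusted p = 0.99985). The highest-ranked upward terms were the degradation of the branched-chain amino acids valine, leucine and isoleucine (44 genes, median log2 fold change 0.35; adjusted p = 6.32e-19), fatty acid beta-oxidation (42 genes, median 0.41; adjusted p = 1.33e-17), fatty acid metabolism (57 genes, median 0.25; adjusted p = 6.76e-15) and the tricarboxylic acid cycle (31 genes, median 0.34; adjusted p = 3.26e-14), each at an adjusted p = 0.99985 with an estimated correlation. Peroxisome genes rose as well (82 genes, median 0.19; adjusted p = 3.22e-09). The highest-ranked downward terms were negative regulation of viral genome replication (28 genes, median -0.61; adjusted p = 3.29e-11), response to virus (57 genes, median -0.31; adjusted p = 1.33e-10) and cytoplasmic translation (174 genes, median -0.31; adjusted p = 3.46e-09), and CCR chemokine receptor binding also fell (20 genes, median -0.69; adjusted p = 0.000117). These 5 terms likewise had an adjusted p = 0.99985 with an estimated correlation. Without group-housed library 3 the count of terms was 144, and without single-housed library 3 it was 157.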

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

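The settings were chosen before the data were examined, except the muscle and B cell covariates, the removal of the 2 libraries with most muscle transcripts and the list test on TMM-normalized log2 CPM, which were added after seeing the data. The count of genes past the threshold was 0 in edgeR as reported, with other size factors, with robust fitting, with a fold threshold and with each library left out (0 to 0), and 0 in limma with 4 pseudocount and filter choices and 3 further fits. It was 207 in DESeq2 (78 higher, 129 lower), 53 in edgeR without a filter on low counts (15 and 38), 203 in limma with library weights (54 and 149), 1028 with the muscle level as a covariate (457 and 571), 319 with the B cell level as a covariate (88 and 231) and 22 without the 2 libraries with most muscle transcripts (8 and 14), against 1259 at an unadjusted p below 0.05. Of the DESeq2 calls, 205 were among the 1028 and 151 also among the 319. The cause of these differing counts was not tested. The replicate numbers did not pair the samples (correlations of deviations 0.12, -0.56 and -0.70 for numbers 1, 2 and 3), and not every library correlated best with its own number. With the replicate block the counts were 0 genes (590 at an unadjusted p below 0.05), 28 lists and 245 terms. The count of lists was 25 as reported, 20 to 29 with each library left out, 0 with an estimated correlation and 0 in fry. The count of terms was 245, 144 to 295 with each library left out, and 0 with an estimated correlation. By construction both tests allow for the correlation between a list's members in these 6 libraries, where the preset is 0.01. In the 17 other alternatives 12 of the 25 list calls held throughout: thermogenic genes (medians 0.29 to 0.77 on the scale of each alternative), brown adipose markers (0.46 to 1.03), mitochondrial fatty acid oxidation (0.37 to 0.67), mitochondrially encoded transcripts (0.46 to 0.78), interferon-stimulated genes (-0.88 to -0.49), inflammatory genes (-0.84 to -0.39), macrophage markers (-0.54 to -0.33), ribosomal proteins (-0.55 to -0.18), endothelial markers (0.17 to 0.41), glyceroneogenesis (0.0090 to 0.33), heat shock genes (-0.40 to -0.14) and immediate-early genes (-0.43 to -0.24). As reported the medians of these 12 lists were, on log2(FPKM + 1) and in that order, 0.43, 0.80, 0.50, 0.63, -0.77, -0.71, -0.47, -0.38, 0.25, 0.16, -0.29 and -0.37. For the other 13 lists they were 0.12 for oxidative phosphorylation, 0.16 for glycolysis, 0.20 for triglyceride synthesis, 0.22 for adipocyte markers, 0.16 for cholesterol synthesis, -0.30 for matrix, 0.23 for lipolysis, 0.14 for de novo synthesis, -0.46 for dendritic cell, -0.003 for adrenergic, 0.035 for clock, -0.22 for progenitor and 0.011 for Schwann lists. Ucp1 kept its sign in 22 alternatives (log2 1.96 to 2.27; adjusted p 3.05e-17 to 0.608), as did Serpinb9b in 21 (-4.47 to -1.42; 4.29e-24 to 0.581). Of 110 named genes 6 changed sign, and of 35 lists 9 changed the direction of their test, all but the Schwann list uncalled as reported; the cause was not tested. For a list, turned means below that the test changed direction, and the value given is the median in that alternative, which in many cases kept its sign. As reported on log2(FPKM + 1) the medians were -0.016 for adipokines, -0.11 for cell cycle, -0.052 for muscle, -0.50 for B cell and -0.32 for T cell markers. On log2 FPKM with a pseudocount of 1 (also without a filter, at a mean FPKM of at least 5 and with robust fitting) and of 0.1, Adipoq was at -0.014 and Acly at -0.059. Without a filter the cell cycle list (-0.098) and the sympathetic axon list (-0.018) turned, and at a mean FPKM of at least 5 adipokines (-0.014) and cell cycle (-0.27). TMM factors on FPKM turned Adrb3 (0.12), cell cycle (0.025) and muscle markers (0.051), and quantile normalization turned Adipoq (-0.0089), Adrb3 (0.074) and cell cycle (-0.0072). Library weights turned Prx (-0.18), Adipoq (-0.28), Lipe (-0.0068), Acly (-0.15) and Pck1 (-0.16), and the tests of B cell (-0.079, adjusted p = 0.996), Schwann (-0.10), muscle (-1.60) and T cell markers (0.020). The muscle covariate turned Adrb3 (0.054) and, with medians as reported, the tests of adipokines (-0.016), cell cycle (-0.11) and muscle markers (-0.052; adjusted p of the 3 lists 0.683, 0.942 and 0.988), and the B cell covariate turned Adipoq (-0.18), Lipe (-0.012), Acly (-0.013), Pck1 (-0.082), mural (-0.12), muscle (-1.46) and T cell markers (0.078). Without the 2 libraries with most muscle transcripts Prx (-0.11), Adrb3 (0.26), Acly (-0.060), adipokines (0.030), cell cycle (-0.16) and muscle markers (-1.39) turned. The replicate block turned Adrb3 (0.050), fry turned cell cycle (-0.11), and TMM-normalized log2 CPM turned cell cycle (-0.022) and the sympathetic axon list (-0.054). With each library left out, values ran from -0.30 to 0.44 for Adrb3, -0.20 to 0.29 for Adipoq, -0.015 to 0.35 for Lipe, -0.059 to 0.19 for Acly, -0.23 to 0.36 for Pck1 and -0.13 to 1.27 for Prx. The list medians ran from -0.11 to 0.21 for mural, -0.27 to 0.17 for adipokines, -0.24 to 0.033 for cell cycle, -0.061 to 0.26 for erythroid, -2.53 to 0.78 for muscle, -0.66 to 0.16 for T cell and -0.74 to -0.0096 for B cell markers. With 3 mice per group and 21410779 to 35318376 counts per library, edgeR recovered 28.6% of 2-fold and 91.7% of 4-fold changes in simulation. It did not call Ucp1 (4.3-fold), Slfn4 (26.6-fold) or Saa3 (48.9-fold) in the real counts, so the simulation does not account for the 0 calls, and Th was not detectable.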

Other observations

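The tests of muscle, adipocyte share, brown fat, lymph node and macrophages below, the splits that count genes without a covariate, and the genes of this paragraph and the next were chosen only after the results were seen. The metallothionein gene Mt2 stood at 14.4, 553 and 99.7 FPKM in group-housed libraries 1, 2 and 3 and between 5.54 and 15.2 FPKM in the single-housed ones (edgeR adjusted p = 0.581); it overlaps a predicted gene on the opposite strand. The acute-phase genes Lcn2 (0.76, 11.9 and 3.17 FPKM against 0.25 to 0.35) and Ptx3 (0.74, 3.12 and 1.6 FPKM against 0.20 to 0.26) had the same order among the group-housed libraries. Socs3, a feedback inhibitor of STAT3 signalling, stood at 12.2 ± 5.70 and 4.28 ± 1.36 FPKM under group and single housing (SD, n = 3 each), while its relative Cish had the opposite sign (log2 fold change 2.58 ± 0.42). Cd5l, a macrophage secreted protein, stood at 19.4 ± 9.86 and 1.28 ± 0.68 FPKM, and the matrix metalloproteinase gene Mmp3 at 50.3 ± 8.92 and 13.3 ± 2.58 FPKM (adjusted p = 0.120). Igha, the constant region of IgA, had higher levels in all 3 single-housed libraries (3.94 ± 1.47 and 17.4 ± 9.43 FPKM), although B cell markers as a list did not pass.

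Members of the macrophage list differed among themselves, and these are examples. Csf1r, the receptor that most tissue macrophages carry, which overlaps Hmgxb3 on the opposite strand, stood at 17.3 ± 1.65 and 17.6 ± 1.49 FPKM and Mrc1, a marker of resident macrophages, at 19.8 ± 3.03 and 16.8 ± 4.14 FPKM. The complement genes C1qa (84.7 ± 4.97 and 60.7 ± 2.06 FPKM) and C1qb (81.3 ± 4.29 and 52.3 ± 3.42 FPKM) and the protease gene Lgmn (57.3 ± 13.7 and 24.9 ± 1.34 FPKM), also of tissue macrophages, had lower means under single housing. Of genes of monocytes, Ccr2 was lower when adjusted over the list alone and Ly6c2 (13.0 ± 5.41 and 9.38 ± 4.37 FPKM) was not. Among thermogenic genes, Elovl3 (5.69 ± 0.60 and 22.1 ± 11.3 FPKM) and Cox7a1 (17.4 ± 1.95 and 44.7 ± 14.9 FPKM) were higher under single housing when adjusted over the list alone. The lineage factors Prdm16 (1.57 ± 0.38 and 1.79 ± 0.07 FPKM) and Ebf2 (4.71 ± 1.08 and 5.52 ± 0.67 FPKM) differed by less (log2 fold changes 0.27 ± 0.22 and 0.31 ± 0.24), as did Adrb3. Fkbp5, a glucocorticoid-induced gene, stood at 8.38 ± 2.80 and 4.83 ± 0.43 FPKM (adjusted p = 0.675).

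The higher level of thermogenic genes could come from other tissue dissected with the fat or from a larger share of adipocytes. Skeletal muscle was present unevenly, with Acta1 at 715 FPKM in single-housed library 3 and 234 FPKM in group-housed library 2. Yet single-housed libraries 1 and 2 held less muscle than group-housed libraries 1 and 2. Over 30 thermogenic genes they exceeded those group-housed libraries by a median of 0.37 on the log2 scale (95% bootstrap interval over genes 0.15 to 0.74). This argues against muscle as the whole cause of the difference between these libraries. The interval treats genes as independent and leaves out variation between mice. Other splits of the 6 libraries into 3 and 3 gave absolute medians of up to 0.63 for this list. Thermogenic genes also exceeded adipocyte markers in median log2 fold change by 0.59 (interval over genes 0.08 to 0.93), which argues against a larger adipocyte share alone. That comparison took in all 6 libraries, among them muscle-rich single-housed library 3, and some thermogenic genes, such as Cpt1b, are also expressed in muscle. A larger adipocyte share together with muscle was therefore not tested. Variation between mice is not in this interval either. Brown fat carried along cannot be told apart from browning in place. The brown depot gene Zic1 had 1, 2 and 13 counts in single-housed libraries 1, 2 and 3, against a limit of detection of 3 counts. These counts did not follow Ucp1, which stood at 274, 174 and 210 FPKM in single-housed libraries 1, 2 and 3. Single-housed library 3 was also the richest in muscle, and a group-housed library had at most 4 counts of Zic1. The level of Zic1 in brown fat was not measured here, so these counts set no bound on a small share of brown fat. Of the 15 brown adipose markers tested 13 lay above 0. Lhx8 (log2 fold change -0.36 ± 0.26) and Epsti1 (-0.74 ± 0.49) lay below, at edgeR adjusted p = 0.844 and 0.830, which does not settle it. Housing itself, for instance heat lost without cage mates, may be the source and is an untested hypothesis.

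The lower level of interferon and inflammatory genes may reflect less lymph node in the single-housed samples, fewer macrophages, or housing itself. Lymph node transcripts were low in single-housed library 3, where Cd79a stood at 50.4 FPKM against 132 to 211 FPKM elsewhere. Single-housed libraries 1 and 2 were set against the 3 group-housed ones. There 52 interferon and inflammatory genes still lay lower than 46 B and T cell markers (difference of medians -0.68, 95% bootstrap interval over genes -0.95 to -0.46). This argues against lymph node content as the whole cause of the difference between these libraries. Here too the interval leaves out variation between mice. Over all libraries these genes lay lower than 24 macrophage markers (-0.34, interval over genes -0.65 to -0.09), which argues against a uniform loss of macrophages alone. The macrophage list shares 1 gene with the mature adipocyte list, and the markers themselves ran from -1.85 (Fcgr1) and -1.02 (Itgam) to 0.36 (Retnla). The comparison therefore cannot decide whether some macrophages or monocytes were fewer, and its interval leaves out variation between mice. Contact such as fighting among group-housed males stays open as a hypothesis and was not tested.

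The 6 libraries can be split into 3 and 3 in 10 ways, which is too few for a share under 0.05. Past the threshold in edgeR the real split gave 0 genes and the highest of the other splits 0, so all 10 gave as many. At an unadjusted p below 0.05 the real split gave 1259 genes and the highest other 2546, and 4 of the 10 splits gave as many. That highest other split put group-housed library 2 and single-housed library 3, which hold the most muscle transcripts, on the same side, and points to a structure of the samples apart from housing. With the muscle level as a covariate the real split gave 1028 genes and the highest other 0 (1 of 10). This covariate takes up the difference in splits that set muscle-rich against muscle-poor libraries. The other splits also leave the housing difference in the residual. The contrast therefore does not measure chance. Lists past the threshold numbered 25 against a highest other of 26 (3 of 10), and terms 245 against 406 (4 of 10). The absolute median log2 fold change was 0.82 against 0.63 for thermogenic genes (1 of 10) and 0.74 against 0.56 for interferon-stimulated genes (1 of 10).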
